A study of Candida albicans with 16 samples.

How the data were processed

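RNA of Candida albicans strain SC5314, a yeast that lives on and infects humans, was compared on 2-colour DNA microarrays between cultures grown with 1 mM L-DOPA and cultures grown without it. Per the labels' protocols, cultures were kept in the dark at 35 °C and sampled at 6, 24, 48 and 72 h, and RNA was reverse transcribed with dye-coupled nucleotides. At each time point the 4 L-DOPA cultures were labelled one by one with Cy5, and each was hybridised against a pool of that time point's control cultures labelled with Cy3, which gives 16 arrays. Per the labels every array had the same dye orientation. The labelling protocol speaks of triplicate L-DOPA samples, whereas the sample titles and the series design give 4 replicates per time point.

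The deposited scanner files hold the intensity of each spot and of its local background in both channels on a linear scale. Per the file headers these intensity values come from QuantArray's histogram method and were neither background subtracted nor corrected for crosstalk between the dyes, and per the series design the slides were read on a ScanArray 4000. The deposited series matrix holds the authors' own log2 ratios of the 2 channels for 6266 genes, whose processing, base and direction are not given in the sources used here. Set against background-subtracted, loess-normalised ratios from the scanner files, these log2 values deposited by the authors correlated with a size of r between 0.802 and 0.998 per array. They ran as Cy3 over Cy5 on 14 arrays and as Cy5 over Cy3 on 2 arrays, replicates 1 and 3 of 6 h. The slopes put them on a base of 2, their medians lay between -0.02 and 0.04, and whether genes were filtered is not known. All signed values below come from the scanner files as log2(Cy5/Cy3), L-DOPA over control, with the direction taken from the dyes in the labels.

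Each array carries 6912 spots in 16 printed blocks of 432: 6458 spots of 6266 genes, 266 spots named empty and 188 control spots of 12 kinds whose content is not given. The genes are named only by systematic identifiers. None of the 6266 identifiers was found in the RefSeq table of the ASM18296v3 assembly, which lists 6263 genes, so the identifiers are not paired with gene names here (0 matched). The gene lists fixed before the data were examined, their camera tests and the rule for naming genes by symbol could therefore not be applied. In their place, 4 identifiers are printed, by a rule made after the data were examined: among genes above the empty spots on at least 8 of the 16 arrays, the highest and the lowest mean ratio over all time points of genes that passed that test with one sign on all replicates, and the highest and the lowest difference between 72 h and 6 h of genes that passed that test.

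Background was corrected with normexp (offset 50), the dyes were normalised within each array by loess (span 0.3) with empty and control spots at weight 0, spots marked by the scanner software (1 to 156 per array) were left out, and spots of one gene were averaged. The files of 72 h replicates 3 and 4 name one slide image and their ratios correlated at r = 0.97 across genes, against 0.11 to 0.38 for other pairs of one time point. Both were quantifications of 1 array, so their mean was used as 1 replicate, which leaves 3 replicates at 72 h and 15 in all. The file header of 24 h replicate 1 calls it a redone array, and it was kept. A gene was called above the empty spots on an array and channel when the intensity of its spot exceeded the 95th percentile of the empty spots there. For a gene with several spots, most of its spots had to exceed this limit.

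Ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, one fit with a mean per time point, 11 residual and 10.1 prior degrees of freedom), with Benjamini-Hochberg adjustment over the 6266 genes and a threshold of 0.05. Each time point's mean was tested against 0. The mean over all time points was tested on the 4 time means, and differences between time points and an F test over the 4 time points were taken from the same fit. As the control pool is 1 sample per time point, a test against 0 leaves out the spread between control cultures. A dye effect of a gene stays in every ratio against 0. It cancels in a difference between time points only where the gene stands equally far above the background at both, and such a difference also holds any difference between the control pools. For 2 channels on one spot, a ratio whose dimmer channel was never above the empty spots is only a bound. Bounds were computed per channel after loess and Aquantile, and they are open to dye bias. The number of arrays limits the precision, and the intensities near the empty spots limit it further.

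The fits were tested on simulated ratios with the spread of the real genes. For the test at 24 h, 79.1% of 67 genes changed by a log2 of 1 were recovered, and for the difference between 72 h and 6 h 46.3% of 67 such genes were, in runs over 6266 genes each. With a log2 of 2 the shares were 98.5% and 90.9% of 66 genes. With a log2 of 0.5 they were 16.4% and 3.0% of 67 genes. The test at 72 h recovered 62.7% of 67 genes changed by 1 and 6.0% of 67 changed by 0.5. The mean over all time points recovered 77.6% of 67 genes changed by 0.5, where the same change was put in at all 4 time points. Calls among 6066 unchanged genes numbered 4 for 24 h, 4 for 72 h, 7 for the difference and 8 for the mean over all time points. The simulated noise was independent between arrays and centred on 0. It held no error shared by the arrays of one control pool and no dye effect. These shares and calls therefore leave out such errors, which the real tests hold. In the 72 h files the Cy5 intensity over the empty spots' median was doubled, for spots above that median only. The median change of the ratio was 0.83 for 100 genes above the empty spots on every 72 h array, against a log2 of 1 put in. For 100 genes above them on none it was 0.20. Spots at or below the median were left unchanged, so the 0.20 can include spots with nothing put in.

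Alternatives fixed before the data were examined were no background correction, plain subtraction, median centring, print-tip loess, scaling between arrays, a filter on dim spots, keeping marked spots, the series matrix, the replicate number as a block, array weights, the quantification day as a block, each array left out, a threshold of 0.01, and each time point's arrays alone. Those added after seeing the data were the empty spots as background, a filter on the empty spots, both 72 h files kept apart, the series matrix with signs matched, the sign of 2 arrays turned, and single quantification days. The split of genes by brightness, the log2 mean of both channels over the replicates, was also added then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.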

Results

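The arrays measured transcript ratios of Candida albicans SC5314 between cultures with 1 mM L-DOPA, an aromatic amino acid that phenol oxidases can turn into melanin, and pooled control cultures of the same age. Ratios were available for 4 L-DOPA cultures at 6 h, 4 at 24 h, 4 at 48 h and 3 at 72 h, where the files of replicates 3 and 4 were quantifications of 1 slide image and were counted as 1 sample. The comparisons ask which transcripts were higher or lower with L-DOPA at each time point and whether the ratios changed over the culture.

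Much of the array was dim. Genes above the 95th percentile of the empty spots numbered 823 to 4522 per array in the Cy3 channel, which held the control pool. In the Cy5 channel, which held the L-DOPA culture, they numbered 234 to 1810. If all genes were like the empty spots, a share of 0.05, or 313 genes, would exceed this limit. The Cy5 counts of 24 h replicate 2 (234), 6 h replicate 4 (276) and 48 h replicate 1 (312) were no higher than that. Being above the empty spots on 1 array is therefore weak evidence of signal. Where sizes are averaged below over genes above them in both channels, at least 1 array per channel was enough. Such sizes can therefore still rest on a channel near the empty spots. Of the 6266 genes, 2762 were above the empty spots in at least 1 channel on 8 or more of the 16 arrays, 169 were so on all 16, and 333 on none. The median gene intensity was 88.5 to 420.2 in Cy3 and 274 to 472 in Cy5, against 55.8 to 262 and 259 to 447 for the empty spots. Compared array by array, the median gene lay above the median of the empty spots in Cy3 on every array. In Cy5 it lay below that median on 6 h replicates 1 and 3, 24 h replicate 2 (273.5 against 281.1) and 48 h replicates 1 and 4. On these arrays the typical gene had no Cy5 signal over the empty spots, which bears on ratios lower with L-DOPA. The 72 h arrays had more genes above the empty spots in Cy3, 2840 to 4522, than the 6 h arrays, with 823 to 2465.

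**Figure D1:**
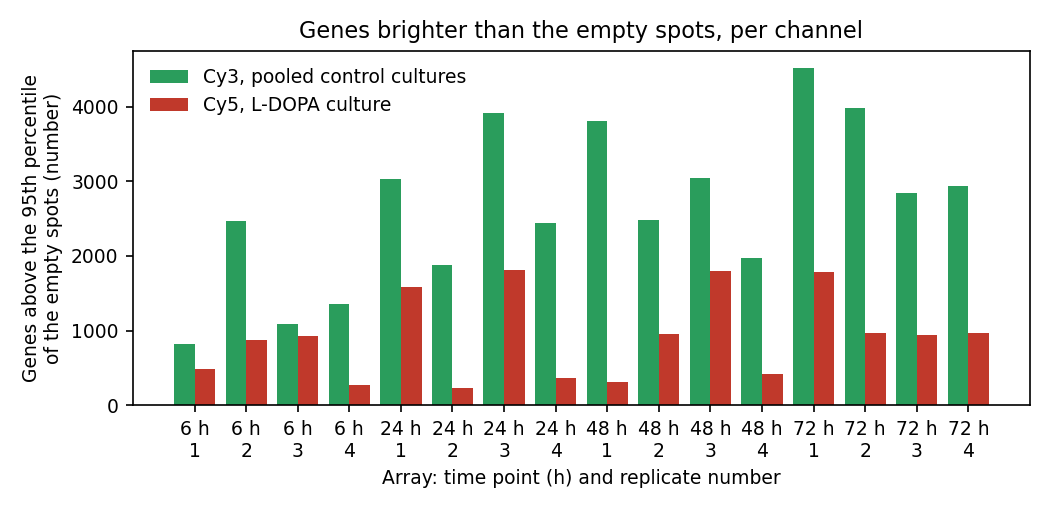
Number of genes (vertical axis) brighter than the 95th percentile of the empty spots on each of the 16 arrays (horizontal axis), in Cy3 (pooled control cultures, green bars) and Cy5 (L-DOPA culture, red bars). The Cy3 bars run from 823 to 4522 and the Cy5 bars from 234 to 1810, and Cy3 is the higher of the pair on all 16 arrays.

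Ratios are given as log2 of L-DOPA over control, so that a positive value is a higher level with L-DOPA, the opposite of the deposited table on 14 of its 16 arrays. Averaged over the 4 time points, 1020 of 6266 genes passed the limma test, 356 higher and 664 lower with L-DOPA. Gene CA01584_01 was the highest among bright genes of one sign, with a mean of 1.37 ± 0.15 (moderated SE by limma, adjusted p = 0.000438; the SD of its 4 time means was 0.52). It was higher with L-DOPA in 15 of 15 replicates, but one sign on all replicates was part of the rule that picked it. Among the 1020 genes, 83 had one sign on all replicates. Gene CA00612_01 had the lowest mean, at -1.31 ± 0.12 (moderated SE by limma, adjusted p = 0.000288, SD of the time means 0.32), and by the same rule was lower in 15 of 15 replicates. In Cy5 it was above the empty spots on 2, 3, 2 and 1 of the 4 files at 6, 24, 48 and 72 h, so its direction is better supported than its size. Of the 1020 genes, 185 were above the empty spots in both channels at every time point, on at least 1 array each, and 11 of these 185 reached a log2 of 1 in size. At the same time 829 of them passed at no single time point. Split at the median brightness of both channels, 583 of the 691 brighter passing genes were lower and 248 of the 329 dimmer ones were higher. The median ratio was -0.11 over all 3133 brighter genes of the array and 0.07 over the 3133 dimmer ones, so this lean is not confined to the genes that passed.

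Per the labels every array had L-DOPA in Cy5, so a dye effect of a gene is part of these ratios. With median centring in place of loess the test gave 1487 genes and CA01584_01 no longer passed, at 0.19 (adjusted p = 0.242), while CA00612_01 stood at -2.19. With the signs of 6 h replicates 1 and 3 turned, as the deposited table has them, 17 genes passed. Both named genes then missed the threshold, CA01584_01 at 1.20 (adjusted p = 0.0547) and CA00612_01 at -0.96 (adjusted p = 0.084). The count was 400 with no background correction and 397 with plain subtraction. On the deposited values it was 500 with signs matched and 4 as they are. It was 612 without 6 h replicate 2, and 620 without 72 h replicate 1.

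At 6 h, 8 genes passed, all lower with L-DOPA, and all 8 were lower on 4 of 4 replicates. Genes that pass this test tend to have one sign on the same replicates. Counts of one sign, here and at the later times, are therefore no separate support. In Cy5, 3 of the 8 were never above the empty spots at this time, so their ratios are only bounds. The other 5, above them in both channels, averaged -1.15 ± 0.18 (SD over genes). All 8 had ratios below 0 at 24, 48 and 72 h as well, but only 2 of them were above the empty spots in both channels at every time point. All 8 were above the empty spots on 8 or more arrays. Of the 2762 genes for which that held, 2048 had a mean ratio below 0, so the shared sign does not by itself show a lasting decrease. CA01584_01 averaged 0.75 ± 0.30 (SD, n = 4, adjusted p = 0.203) and CA00612_01 -1.21 ± 1.15 (SD, n = 4, adjusted p = 0.0937) at this time, and neither passed. With arrays scaled to one spread 296 genes passed, 47 higher and 249 lower, and with array weights 166. With median centring or the 6 h arrays alone 0 passed (limma, 670 genes at an unadjusted p under 0.05 in the main setting). The count was 84 without 6 h replicate 1, 13 without replicate 2, 1 without replicate 3 or replicate 4, 3 without 24 h replicate 4, and 4 without 48 h replicate 3.

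At 24 h, 14 genes passed, 7 higher and 7 lower, each with one sign on 4 of 4 replicates. Of the lower genes 5 were never above the empty spots in Cy5, and of the higher genes 1 was never above them in Cy3, so these ratios are only bounds. Another 1 of the higher genes was above them in Cy3 only, the control channel, so its ratio gives no size. The 5 higher genes above them in both channels averaged 1.03 ± 0.22 (SD over genes). CA01584_01 was among the genes that rose, at 1.19 ± 0.76 (SD, n = 4, adjusted p = 0.0424). CA00612_01 averaged -1.11 ± 0.41 (SD, n = 4, adjusted p = 0.0803) and CA00288_01 0.93 ± 0.41 (SD, n = 4, adjusted p = 0.0581), short of the threshold. Median centring gave 974 genes, 267 higher and 707 lower. With the quantification day as a block 14 passed, 3 higher and 11 lower, of which 5 were among the 14 of the main setting. Scaling between arrays gave 3, 2 higher and 1 lower, and print-tip loess gave 0. Leaving out 24 h replicate 1, a redone array per its file header, left 2 genes, and leaving out replicate 2, 3 or 4 left 0 (1175 genes had an unadjusted p under 0.05 with all arrays). The count was 36 without 6 h replicate 3, 48 without 48 h replicate 2 and 7 without 72 h replicate 2.

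At 48 h, 156 genes passed, 55 higher and 101 lower with L-DOPA, and 146 of them had one sign on 4 of 4 replicates. Above the empty spots in both channels, on at least 1 array each, were 35 of the genes that rose, with a mean of 0.96 ± 0.29 (SD over genes), and 37 of those that fell, with -0.85 ± 0.14. Of these 72 genes, 18 reached a log2 of 1 in size. CA01584_01 rose by 1.59 ± 0.72 (SD, n = 4, adjusted p = 0.00961), CA00288_01 by 0.99 ± 0.41 (SD, n = 4, adjusted p = 0.0274) and CA10218_01 by 0.67 ± 0.31 (SD, n = 4, adjusted p = 0.0475). CA00612_01 was lower at -1.15 ± 0.65 (SD, n = 4, adjusted p = 0.0475). Of the 101 lower genes, 64 were never above the empty spots in Cy5 at this time, and of the 55 higher genes 7 were above them in Cy5 only, so for these the ratio is only a bound. Another 13 of the higher genes were above them in neither channel, and their ratios give no size.

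The 48 h count was 1 with no background correction and 6 with scaling between arrays (2 higher, 4 lower). It was 610 with median centring (84 higher, 526 lower), 0 on the 48 h arrays alone and 79 with the quantification day as a block. It was 0 without 48 h replicate 2, 11 without replicate 4 and 52 without replicate 1. Without arrays of other times it was 81 (6 h replicate 4), 93 (6 h replicate 1), 93 (24 h replicate 1) and 103 (24 h replicate 3).

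At 72 h, 177 genes passed, 65 higher and 112 lower, and 173 of them had one sign on 3 of 3 replicates. Above the empty spots in both channels, on at least 1 array each, were 41 of the genes that rose, with a mean of 1.09 ± 0.34 (SD over genes), and 68 of those that fell, with -1.34 ± 0.39. Of these 109 genes, 73 reached a log2 of 1 in size. CA01584_01 rose by 1.94 ± 0.29 (SD, n = 3, adjusted p = 0.000463), a 3.84-fold higher level, and CA00288_01 by 1.62 ± 0.18 (SD, n = 3, adjusted p = 0.00085), a 3.07-fold higher level. CA10218_01 was at -2.33 ± 0.54 (SD, n = 3, adjusted p = 9.97e-07) and CA00612_01 at -1.79 ± 0.56 (SD, n = 3, adjusted p = 0.00668). In Cy5 each of the last 2 genes was above the empty spots on 1 of the 4 files, so no fold is given for them. Both are nevertheless among the 68 lower genes and the 73, as 1 array per channel was enough there. The mean of -1.34 and the 73 can therefore hold other sizes that are as uncertain. Of the 112 lower genes, 44 were never above the empty spots in Cy5, and of the 65 higher genes 10 were above them in Cy5 only, so these ratios are only bounds. Another 14 of the higher genes were above them in neither channel, and their ratios give no size.

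Scaling between arrays left 40 genes at 72 h, 12 higher and 28 lower. Median centring gave 379, 91 higher and 288 lower, and no background correction left 17. The count was 85 without 72 h replicate 1, 86 without replicate 2, and 75 without the image of replicates 3 and 4.

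**Figure D2:**
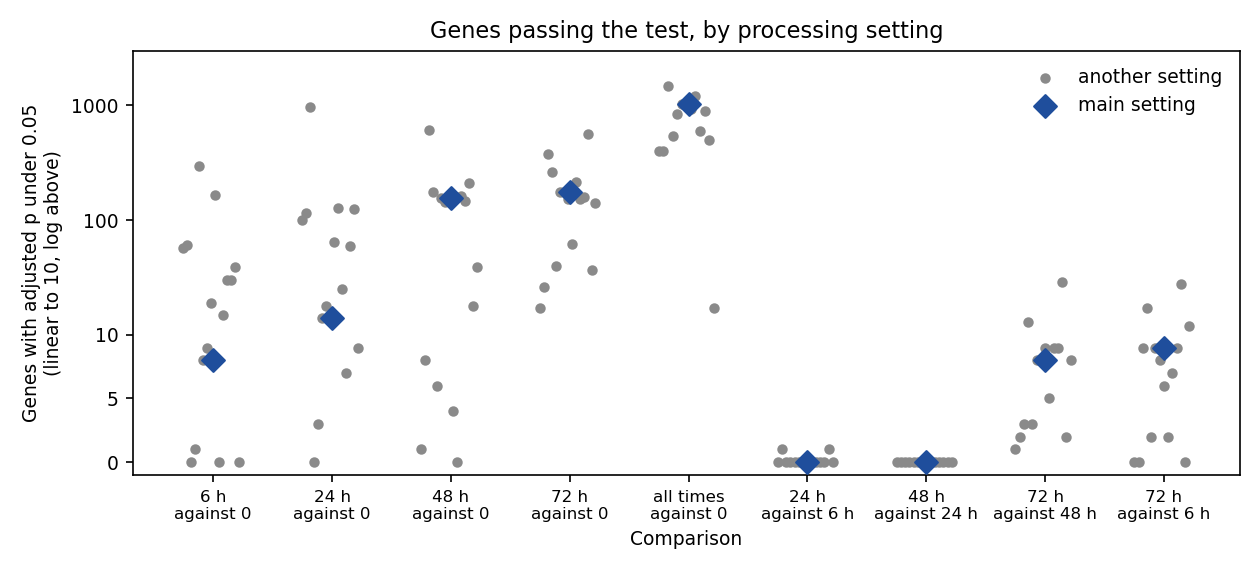
Number of genes with an adjusted p under 0.05 (vertical axis, linear to 10 and logarithmic above) for each time point against 0, the mean over all times and 4 differences between times (horizontal axis), in the main setting (blue diamonds) and other processing settings (grey points, without single arrays left out, other thresholds, day blocks and the deposited values with their signs as they are). The main counts are 8, 14, 156 and 177 at the 4 time points, 1020 over all times, and 0, 0, 8 and 9 for the differences, and the grey points spread widely around the counts of single time points.

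Genes that passed at one time mostly had the same sign at the others. Of the 177 genes of 72 h, 151 had the same sign at 48 h, 158 at 24 h and 146 at 6 h. The lists of 48 h and 72 h shared 13 higher genes, against 0.57 for independent lists, and 15 lower genes, against 1.81. In opposite directions 1 gene passed. The lists were not independent, as both came from one fit with one spread per gene and both hold any dye effect. Their overlap therefore does not by itself show a shared response. Across genes, the time means correlated at r = 0.41 to 0.60, and genes are not independent replicates. Between single arrays the mean correlation across genes was 0.24 for pairs of one time point and 0.22 for pairs of different time points, a difference of 0.03 (two-sided permutation test of the arrays' time labels, 100000 resamples, p = 0.037). Different control pools were used at each time, but the dye orientation was shared per the labels. Arrays of one time point shared a control pool, and some shared a quantification day. Either could give the difference of 0.03 without a response to L-DOPA.

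**Figure D3:**
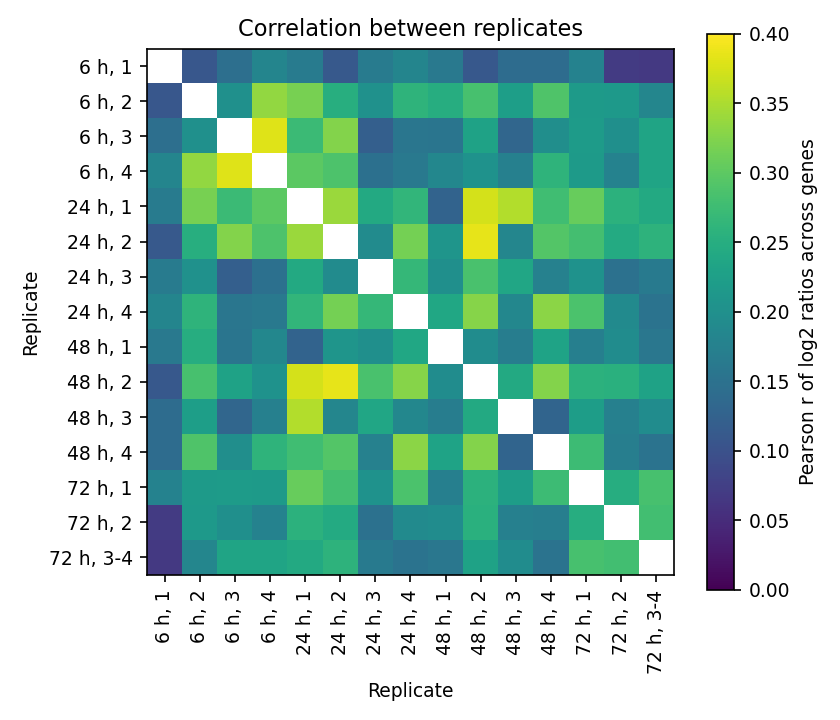
Pearson correlation of log2 ratios across genes between the 15 replicates (both axes, ordered by time point in h and replicate number; 72 h, 3-4 is the mean of 2 files of one image), with colour from 0 to 0.4. All pairs lie above 0, with a mean of 0.24 within time points and 0.22 between them.

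Few genes passed for a difference between time points, and these tests could miss many differences. On simulated ratios, 46.3% of 67 genes with a difference of 1 were recovered for 72 h against 6 h, and 47.8% for 48 h against 24 h. With a difference of 0.5 the shares were 3.0% and 4.5%. A constant dye effect cancels in these tests only where a gene stood equally far above the background at both times, and more genes were above the empty spots in Cy3 at 72 h than at 6 h. From 48 h to 72 h, 8 genes passed, all with a lower ratio at 72 h. The 5 of them above the empty spots in both channels at every time averaged -0.38 at 6 h, -0.25 at 24 h, 0.14 at 48 h and -1.94 at 72 h. Of the 8, 7 were above the empty spots in both channels at 48 h and 7 at 72 h, on at least 1 array each. The adjusted p of the 8 ran from 1.63e-06 to 0.0256. CA10218_01 was among them: its ratio was -0.11 at 24 h, 0.67 at 48 h and -2.33 at 72 h (72 h against 48 h, limma, n = 3 and 4, adjusted p = 1.63e-06). That gene was above the empty spots in both channels on 4 of 4 arrays at 48 h, but at 72 h in Cy5 on 1 of the 4 files only, so the size of its drop is uncertain. It passed this test in all 14 other settings in which it was computed and that changed the data or the threshold. It also passed in 15 of 15 runs with an array left out, with adjusted p of up to 0.0396 over settings and runs. Only runs without a 48 h or 72 h array change the difference itself, and the others change only its spread. Print-tip loess gave 13 genes, 2 higher and 11 lower. Scaling between arrays gave 3, median centring 3 and no background correction 1. Leaving out 48 h replicate 3 gave 15.

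Between 6 h and 72 h, 9 genes passed, 3 with a higher and 6 with a lower ratio at 72 h. The 3 higher genes averaged 0.69 at 24 h, 0.78 at 48 h and 1.32 at 72 h. At 6 h 1 of them was above the empty spots, in Cy3 only, so 6 h ratios are not given for them. Of the 6 lower genes, 3 were above the empty spots in both channels at 6 h. CA00288_01 (adjusted p = 0.0366, limma, n = 3 and 4) and CA10218_01 (adjusted p = 0.000773) passed this test. At 6 h CA00288_01 was above the empty spots in neither channel on any array, and CA10218_01 on 1 of 4 arrays in Cy3 and on none in Cy5. Their differences from 6 h therefore have no size. CA01584_01 missed the threshold for this difference, at 1.19 ± 0.38 (moderated SE, adjusted p = 0.355). CA00288_01 was short of the threshold in 9 of 14 other settings, among them no background correction (adjusted p = 0.502) and scaling between arrays (adjusted p = 0.313), and in 7 of 15 runs with an array left out.

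The count for 72 h against 6 h was 0 with no background correction and with plain subtraction (limma, 529 genes at an unadjusted p under 0.05 in the main setting). It was 2 with scaling between arrays (1 higher, 1 lower), 9 with median centring, all lower, and 17 with print-tip loess. Without single arrays it was 2 (6 h replicate 1), 5 (6 h replicate 2), 1 (6 h replicate 4), 14 (24 h replicate 2), 1 (24 h replicate 3), 3 (24 h replicate 4), 3 (72 h replicate 2) and 2 (the image of 72 h replicates 3 and 4).

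No gene passed for 24 h against 6 h (limma, 302 genes at an unadjusted p under 0.05, where 313 are awaited by chance) or for 48 h against 24 h (268 genes). The smallest adjusted p was 0.811 and 0.512. The 24 h and 48 h arrays shared 2 quantification days, and with the day as a block 0 genes passed. Within the days 7 and 0 did, each resting on a single array of one time point that was assumed to vary like the others. All 6 h arrays were quantified on a day of their own, as were those of 72 h apart from a repeat of one image, so for these times day and time point cannot be told apart. An F test over the 4 time points gave 3 genes (adjusted p from 2.02e-05 to 0.00859), CA10218_01 among them, and all 3 also passed for 72 h against 48 h and against 6 h. That count was 1 without 72 h replicate 1, without 72 h replicate 2 or without the image of replicates 3 and 4. It was 5 to 8 without 6 h replicate 1, 2 or 3, 24 h replicate 2, 48 h replicate 2 or 1 file of the image of 72 h replicates 3 and 4.

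**Figure D4:**
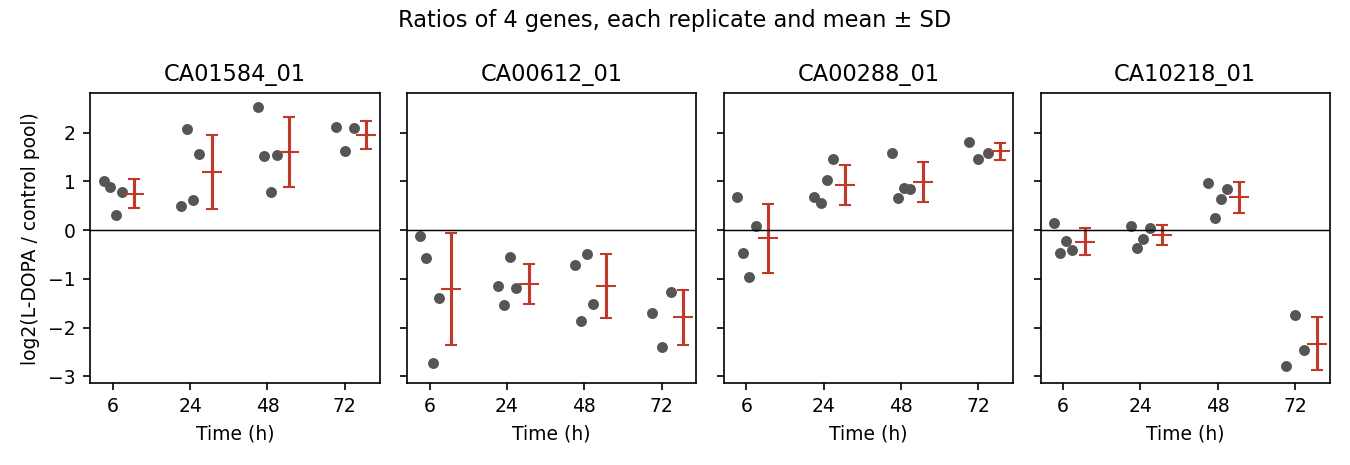
Log2 ratio of L-DOPA over the control pool (vertical axis) at 6, 24, 48 and 72 h (horizontal axis) for the 4 named genes, with each replicate as a grey point and the mean ± SD in red (n = 4, and 3 at 72 h). CA10218_01 lies at 0.67 on average at 48 h and at -2.33 at 72 h. By the rule that picked them, CA01584_01 lies above 0 and CA00612_01 below 0 on all 15 replicates.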

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

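The tests of other splits of the arrays were planned, and the tests of explanations below were chosen after the results were seen.

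Ratios differed between time points for 8 genes from 48 h to 72 h, 9 genes from 6 h to 72 h and 3 genes among the 4 time points. In the first, 1 of 35 splits of the same arrays, the real one, gave as many genes, and the highest other split gave 3. In the second it was again 1 of 35, with 2 as the highest other. For the F test over the 4 time points 2 of 100 splits reached 3 genes, and the highest other was 3. The share of splits was under 0.05 in each of these 3 tests, without correction for the number of tests, and 1 of 35 is the smallest share that 35 splits allow. The other splits mix arrays of different control pools. They therefore cannot exclude a chance difference between the pools, each of which is a single sample. For 24 h against 6 h and 48 h against 24 h the real count was 0, which all 35 of 35 splits must reach, with 0 and 1 as the highest other, so the splits say nothing there. These differences hold any difference between the control pools and, for 6 h and 72 h, between the quantification days.

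A pattern of ratios was shared by the arrays of all time points, with a mean correlation of 0.216 between arrays of different time points. Of position on the slide as its source, print-tip loess gives a measure: 79.8% of the mean size of the 1020 genes' ratios was left after print-tip loess, and 1019 of them kept their sign. With print-tip loess 540 genes passed over all times, of which 480 were among the 1020. Empty spots also correlated, at 0.122, so a share by position stays open. A gene-specific dye effect and a response to L-DOPA shared by the time points cannot be told apart, since 0 arrays have the other dye orientation per the labels. Either could produce the pattern.

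More genes passed at 48 h and 72 h than at 6 h and 24 h, with a ratio of 15.1 between the totals. A spread of the log ratios that differs between arrays is a candidate explanation: with arrays scaled to one spread the ratio was 0.154. The counts then went from 8 to 296 at 6 h, 14 to 3 at 24 h, 156 to 6 at 48 h and 177 to 40 at 72 h. Scaling would also shrink a response that widened the ratios of the late arrays. It therefore cannot tell such a response from a technical spread. The background correction is another candidate, as without it the ratio was 0.115, and with plain subtraction 0.193. Other settings went both ways. The ratio was 7.9 with the empty spots as background, 8.3 with only genes above the empty spots and 440 with print-tip loess. It was 1.02 with median centring and 0.286 with array weights. A response to L-DOPA growing with time stays open. Of the 304 genes passing at 48 h or 72 h, 2.96% also passed for 72 h against 6 h or among the 4 time points, and 2.22% of 45 genes did after scaling.

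The deposited table turns the signs of 2 of the 6 h arrays against the other 14. In log2(Cy5/Cy3) from the scanner files, these arrays correlated with the other 13 replicates at a mean of 0.177 ± 0.07 (SD over 26 pairs), where swapped dyes together with a shared response to L-DOPA would give values below 0. A sign turned in the table only is consistent with 100% of the pairs lying above 0. Swapped dyes together with ratios that come from a dye effect would give the same picture and stay open.

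Among 30 groups of 4 arrays or gene values, 4 held an array far from the others, where chance gives about 5%. The median gene intensity in Cy3 was 193 on 6 h replicate 1 against 108 to 114 on the other 6 h arrays, 420.2 on 24 h replicate 1 against 88.6 to 124, and 139.9 on 48 h replicate 4 against 88.5 to 96.0. In Cy5 it was 327 on 24 h replicate 1 against 274 to 279. Per its file header 24 h replicate 1 is a redone array.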

How the results depend on the processing

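Alternatives were fixed before the data were examined, except those named here as added after seeing the data. Counts of genes at single time points depended on the processing under most alternatives, and the cause was not tested unless named. Counts are given for 6 h, 24 h, 48 h, 72 h and all times against 0, then for 72 h against 48 h, 72 h against 6 h and among the 4 time points. In the main setting they were 8, 14, 156, 177 and 1020, then 8, 9 and 3. With no background correction they were 57, 100, 1, 17 and 400, then 1, 0 and 0. Plain subtraction gave 61, 115, 8, 26 and 397, then 2, 0 and 0, and 1 for 24 h against 6 h. Median centring gave 0, 974, 610, 379 and 1487, then 3, 9 and 2. Print-tip loess gave 1, 0, 175, 265 and 540, then 13, 17 and 11. Scaling between arrays gave 296, 3, 6, 40 and 843, then 3, 2 and 2. Array weights gave 166, 65, 4, 62 and 936, then 5, 2 and 6. The deposited values as they are gave 0, 56, 0, 28 and 4, then 2, 1 and 1, and 2 for 24 h against 6 h. A threshold of 0.01 gave 2, 0, 3, 48 and 259, then 7, 1 and 3, by its construction. Each time point's arrays alone gave 0, 127, 0 and 215. The quantification day as a block gave 14 at 24 h, of which 5 were among the 14 of the main setting, and 79 at 48 h, of which 54 were among the 156. Keeping marked spots left all counts within 1.5 times. The filter on dim spots removed none of the 6458 gene spots and says nothing.

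Of the alternatives added after seeing the data, the empty spots as background gave 15, 25, 162, 153 and 1211, then 9, 7 and 2. Only genes above the empty spots gave 30, 7, 148, 159 and 598, then 9, 9 and 7. Both 72 h files kept apart, which counts one image as 2 replicates, gave 30, 59, 211, 563 and 901, then 29, 28 and 20. The deposited values with signs matched gave 39, 125, 18, 37 and 500, then 2, 0 and 0, and 1 for 24 h against 6 h. The sign of 6 h replicates 1 and 3 turned gave 0, 9, 39, 141 and 17, then 8, 12 and 3. Within quantification days, 48 h against 24 h gave 7 and 0. In all other settings 24 h against 6 h and 48 h against 24 h gave 0 genes by limma, with 96 to 688 genes at an unadjusted p under 0.05. Where another count was 0, between 134 and 1175 genes had an unadjusted p under 0.05.

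Replicate numbers did not pair the arrays: deviations of same-numbered arrays of different time points correlated at -0.14 to 0.09, none of 21 pairs (0) lay over 0.1, and 3 of 15 arrays correlated best with their own number. With the number as a replicate block the counts were 19, 15, 150 and 153, then 9, 6 and 5, and the mean over all times was not run with it.

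With 1 array left out, counts ranged from 1 to 84 at 6 h (highest without 6 h replicate 1), 0 to 48 at 24 h, 0 to 228 at 48 h (lowest without 48 h replicate 2), 75 to 223 at 72 h, 612 to 1037 over all times, 6 to 15 for 72 h against 48 h, 1 to 14 for 72 h against 6 h and 1 to 8 among the 4 time points, with 0 throughout for 24 h against 6 h and 48 h against 24 h.

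CA10218_01 kept its direction and its side of the threshold for 72 h against 48 h in all 14 other settings, not counting the filter that removed no spot, and in 15 of 15 runs without an array. For 72 h against 6 h it kept both in 11 of 14 settings and 15 of 15 runs without an array, and CA00288_01 in 5 of 14 settings and 8 of 15 runs. Runs without an array of a time outside the difference change only the spread. At 6 h neither gene was above the empty spots in Cy5 on any array. Over all times CA01584_01 kept them in 11 of 13 and CA00612_01 in 12 of 13. None of these reversed. For the deposited values as they are, single genes were not computed, because the direction there is mixed. The gene list tests with their alternatives (estimated correlation, fry, other normalisations) were not run, since the identifiers are not paired with names here. Low signal over the empty spots limits all ratios. In the spike at 72 h, a log2 of 1 came out as 0.83 for bright genes. Dim genes changed by 0.20, but their spots at or below the median of the empty spots had nothing put in.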

Other observations

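On the array 12 genes had 17 spots each. By the rule that most spots of a gene exceed the limit, 9 of the 12 genes were above the empty spots on only 0 to 2 of the 16 arrays and 3 on 8 to 12. These numbers of arrays are not directly comparable with those of genes with 1 spot. The median SD of the log2 ratio between copies on one array was 0.32, against a median SD between replicates of 0.38 for all genes, of which 6254 had 1 spot. The means over 17 copies had a median SD between replicates of 0.13. None of the 12 genes (0) passed at any single time point or for any difference between 2 time points, and 1 passed over all times. For the 9 genes rarely above the empty spots by that rule, this says little.

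Correlations between replicates went with brightness. The mean correlation between pairs of replicates was 0.42 over the 169 genes above the empty spots on all 16 arrays, 0.18 over the 2593 genes above them on 8 to 15 arrays, 0.15 over the 3171 genes above them on 1 to 7 arrays, and 0.06 over the 333 genes never above them. Over the 266 empty spots it was 0.12, and over the 188 control spots 0.04. The median of a control kind lay between 0.945 and 1.28 times that of the empty spots in Cy3 (median over arrays).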
